A study of Rattus norvegicus with 44 samples.

How the data were processed

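Choroid plexus and trunk blood of male Sprague-Dawley rats were profiled on Agilent arrays with 1 dye. Per the labels' protocols, total RNA was extracted with Tri Reagent and labelled with Cy3 by the Agilent Quick Amp kit. Each choroid plexus array carries a pool of 3 rats and each blood array 1 rat, per the labels. The scanner software, the background correction and the rule that left cells blank are not given in the sources used here. Meninges arrays that the study's design mentions were not analysed here.
The values are the authors' deposited intensity values on a linear scale, in a single file of 14055 probes by 44 arrays with 0 columns from outside the series. No label states their normalization. The quantiles of the values are close within the 24 arrays of 3 h and within the 20 arrays of 1 day (medians 139 to 146 and 165 to 171, 75th percentiles 577 to 582 and 618 to 634) and differ between these sets. The arrays appear to have been normalized in 2 sets, each with both tissues. A comparison across the sets therefore mixes time with the set. Intensities below 1 would have been set to 1 before log2 was taken, blank cells stayed missing, and the values were otherwise used as deposited, since the medians of the arrays lay within 0.246 log2 in choroid plexus and 0.299 in blood.
Of the probes, 12926 had 1 gene symbol in the platform annotation, 0 had several and 1129 had none. Symbols were taken through the accession for 11481 probes, were current for 1363, were updated through a synonym for 78 and were kept as given for 4. Of the resulting 10412 genes, 2210 had several probes, and the probe with the highest mean over all 44 arrays stood for the gene. Where another probe of a named gene gave a clearly different value it is stated.
Groups were taken from the treatment, tissue and time labels. The 4 choroid plexus EIH pools of 1 day are titled as controls, but source and treatment labels call them EIH, and they were used as EIH. The blood samples carry a tag that mentions striatum, while the protocol describes trunk blood. There was no choroid plexus saline group of 1 day among the arrays analysed here, so both 1 day groups were set against saline at 3 h. Replicates were numbered in accession order and pair nothing.
Each gene was fitted with limma (version 3.58.1; R 4.3.3, data.table version 1.17.8) with a mean per group, over the 20 choroid plexus arrays or the 24 blood arrays, followed by empirical Bayes moderation. The comparison of tissues used both saline groups of 3 h, and differences between tissues in a treatment effect used all 44 arrays. A gene was tested where each compared group had at least 2 values, and was called at a Benjamini-Hochberg adjusted p under 0.05 within a comparison. Each of the 31 gene lists was tested with camera at a preset correlation of 0.01, adjusted over the lists of a comparison, and again with a correlation estimated from the data. Fry, a rotation test of whether the members of a list move one way, was run on genes without blanks. Figures were drawn with matplotlib 3.10.9 and pandas 2.3.3 in Python 3.11.15.
The groups, the tests, the gene lists, the rule for named genes and the main alternatives were fixed before the data were examined. By that rule, each comparison with saline names the 8 largest rises and 6 largest falls among called genes whose treated arrays all lay beyond every control array, leaving out predicted loci. It adds up to 4 members of each list that was called or had 3 or more called members, and a fixed set of marker genes (in choroid plexus Ttr, Kl, Aqp1, Slc4a5, Cldn1, Hspa1b, Hspb1, Dnajb1, Fkbp5, Mt1a, Lcn2, Ccl2, Il1b and Pdk4, in blood Hspa1b, Hspb1, Dnajb1, Fkbp5, S100a8, Cxcr2, Cd3e, Prf1 and Alas2, with 1 other gene not reported here). Other comparisons name the 4 largest rises and falls. The text prints a part of the genes so chosen.
The alternatives were 3 other normalizations (quantile within the tissue, the same median, the same 75th percentile), leaving out the 25% of genes with the lowest mean, an intensity trend with a robust spread, array weights, fitting only the compared groups, the mean over probes, every probe alone, a minimum of 1.5-fold, a plain equal-variance test per gene, leaving out each array, and leaving out pools with a recurring rat. Added after seeing the data were fits without choroid plexus AMPH 1 day replicate 2, without blood saline 1 day replicate 4, with genes measured on every array, and without liver and salivary gland genes. For comparisons between tissues, arrays that share a rat as a random replicate block were added as well.
The steps were tested on simulated data with the spread of the real arrays and 200 changed genes. In the simulation of choroid plexus EIH at 3 h, 46% of genes changed 2-fold and 76% of genes changed 4-fold were called, and in that of blood EIH at 3 h 14% and 53%. For shared saline arrays, 100 simulations of unchanged groups gave the correlation that sharing alone produces at equal group spread.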

Results

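Transcript levels were measured in the choroid plexus, the epithelial tissue that secretes cerebrospinal fluid, and in trunk blood of male rats. There were 44 single-colour arrays in 11 groups of 4. The rats had received saline, had been made hyperthermic by a hot environment (environmentally-induced hyperthermia, EIH) or had received neurotoxic doses of amphetamine (AMPH). They were sampled 3 h or 1 day after exposure. Choroid plexus was hybridised as 20 pools of 3 rats each: saline at 3 h, and EIH and AMPH at both times. Blood was hybridised as 24 samples of single rats, with saline, EIH and AMPH at both times. By their labels, 17 of the blood rats also gave tissue to a choroid plexus pool, and 5 rat numbers recur over 7 pools, so not all pools are independent. Of these numbers 3 recur in pools of different time or treatment, and 2 blood rats are listed in a pool of another time. If each number stands for 1 rat, some of these numbers or labels are wrong, and which ones is unknown. The stated purposes were to learn how the choroid plexus works under control conditions, what damage and protective responses it makes to each exposure, and how immune responses compare across tissues.
Median intensity per array was 139 to 146 on the 24 arrays of 3 h and 165 to 171 on the 20 arrays of 1 day, so the values appear to fall into 2 separately scaled sets. Blank cells made up 3.05% of the choroid plexus values and 8.57% of the blood values, and the number of arrays limits the precision. Differences are on the log2 scale, as estimate ± standard error from limma, with 4 arrays against 4 unless another n is stated. Adjusted p refers to Benjamini-Hochberg adjustment within a comparison. All p-values measure the spread between these pools and samples. Each gene list is given with its median log2 difference and an adjusted p from camera at a preset correlation. Calls hold with a correlation estimated from the data unless an adjusted p above 0.05 with that estimate follows.
Under saline at 3 h, choroid plexus and blood differed in the genes that define each tissue. Ttr, which encodes the transthyretin secreted into cerebrospinal fluid, was higher in choroid plexus by 11.41 ± 0.99 (adjusted p = 6.4e-05; n = 4 and 3). Sostdc1 was higher by 11.16 ± 0.65, Cnmd by 10.76 ± 0.46 (n = 4 and 3) and the potassium channel gene Kcnj13 by 10.76 ± 0.16 (n = 4 and 2). Ttr and Sostdc1 lay at the upper end of the scale in choroid plexus, so their differences are compressed. The erythroid gene Hemgn fell by 8.83 ± 0.39 from blood to choroid plexus, Pla2g2a by 8.93 ± 0.22 and Fgf17 by 8.77 ± 0.26. The lipoxygenase gene Alox15 fell by 8.99 ± 0.21 (adjusted p = 8.1e-08).
Of 23 measured members of the choroid plexus epithelium list, 21 were higher in choroid plexus (median 7.64, adjusted p = 2.9e-07). In the ependyma and cilia list 8 of 9 were higher (median 4.64, adjusted p = 0.000499). In the list for cerebrospinal fluid secretion and ion transport 15 of 23 were higher and 3 lower (median 3.30, adjusted p = 0.00885). Barrier transporter and junction genes (17 of 26 higher; median 1.88, adjusted p = 0.00156) and cholesterol synthesis genes (12 of 18 higher; median 1.63, adjusted p = 0.00117) were also higher as lists. Stroma and meninges (median 3.62, adjusted p = 0.00945) and heat shock and chaperone genes (median 1.61, adjusted p = 0.000376) were higher too. So were endoplasmic reticulum (ER) stress (median 1.61, adjusted p = 0.0291) and fatty acid oxidation genes (median 1.17, adjusted p = 0.00468). These 4 lists had adjusted p = 0.229, 0.229, 0.234 and 0.0852 with an estimated correlation.
Markers of blood cells had the opposite order. All 13 erythroid genes were lower in choroid plexus (median -6.44, adjusted p = 1.9e-09), as were 9 of 10 platelet genes (median -5.90, adjusted p = 7.3e-06) and 14 of 17 T cell genes (median -5.05, adjusted p = 4.7e-07). B cell genes (11 of 12; median -3.38, adjusted p = 1.8e-05) and NK and cytotoxic genes (14 of 19; median -3.46, adjusted p = 4.7e-06) were lower. Neutrophil (13 of 19; median -4.55, adjusted p = 4.6e-05) and MHC class II genes (10 of 11; median -2.65, adjusted p = 1.5e-05) were lower as well. Cytokine, chemokine and adhesion genes were lower too (median -1.18, adjusted p = 0.00398). Interferon response (median -1.56, adjusted p = 6.4e-06), macrophage and monocyte (median -1.44, adjusted p = 0.00214) and immediate early genes (median -1.73, adjusted p = 0.00156) were lower with the preset correlation. These had adjusted p = 0.157, 0.229 and 0.229 with an estimated correlation. The same held for cell cycle (median -0.96, adjusted p = 0.00121) and p53 and apoptosis genes (median -1.29, adjusted p = 0.0227), with adjusted p = 0.234 and 0.375 with an estimated correlation. No call was made for circadian clock (median 0.80, adjusted p = 0.145), neuron (median 0.64, adjusted p = 0.768), endothelium (median 1.31, adjusted p = 0.154), mural (median 1.25, adjusted p = 0.590) or glia genes (median 0.93, adjusted p = 0.375). Nor was there one for glucocorticoid response (median -0.03, adjusted p = 0.827), metallothionein and oxidative stress (median -0.36, adjusted p = 0.287), acute phase and complement (median 0.81, adjusted p = 0.590) or hypoxia and glycolysis genes (median 0.89, adjusted p = 0.145). In all, 5581 of 9925 genes passed, 3166 higher in choroid plexus and 2415 lower, and 4462 of them differed at least 2-fold.
At 3 h after EIH, inducible chaperone genes rose in the choroid plexus. Hspa1b, the stress-inducible Hsp70 gene, rose by 6.43 ± 1.09 (adjusted p = 0.0214). The small heat shock protein gene Hspb1 rose by 4.35 ± 0.72, with its highest EIH array near the upper end of the scale at 15.97. A second probe of Hspa1b gave 1.85, and EIH replicate 3 lay at 11.01 against 15.27 to 15.98 on the other EIH arrays, the highest at the upper end of the scale, so no fold change of this gene is given here or below. Hmox1, the inducible heme oxygenase gene, rose by 3.90 ± 0.61 (15.0-fold, 95% interval 6.12 to 36.5), the transcription factor genes Cebpd and Atf3 by 3.10 ± 0.62 and 3.07 ± 0.53, and Rgs1 by 3.01 ± 0.59. The Hsp110 chaperone gene Hsph1 rose by 2.78 ± 0.51, the Hsp90 cochaperone gene Ahsa2 by 2.53 ± 0.42, the ER disulfide isomerase gene Pdia4 by 2.18 ± 0.43 and Hsp90ab1 by 1.37 ± 0.22. Adjusted p of these genes ran from 0.0214 to 0.0376. The single gene that fell was Slc35b2, by 0.77 ± 0.14 (adjusted p = 0.0249).
The heat shock and chaperone list rose as a whole (median 1.63, adjusted p = 8.0e-29, and 0.0302 with an estimated correlation). Of its 23 members 10 passed over all genes and 21 adjusted over the list alone. There were rises in 5 other lists with the preset correlation. ER stress genes (median 0.83, adjusted p = 3.3e-12) had 13 of 19 members up adjusted over the list alone, and immediate early genes (median 1.25, adjusted p = 3.3e-12) 16 of 23. Cytokine, chemokine and adhesion genes (median 0.91, adjusted p = 2.9e-09) had 13 of 27, glucocorticoid response genes (median 0.75, adjusted p = 8.2e-07) 8 of 22 and p53 and apoptosis genes (median 0.48, adjusted p = 1.1e-05) 6 of 21. The adjusted p of these lists with an estimated correlation were 0.110, 0.0840, 0.0840, 0.110 and 0.0840. Among their members that did not pass over all genes, the neutrophil chemoattractant genes Cxcl1 and Cxcl2 stood at 4.33 ± 0.91 and 3.31 ± 0.82 (n = 4 and 3 for both), Ccl2 at 2.20 ± 0.64 and Il1b at 1.55 ± 0.44. Nr4a3 stood at 2.39 ± 0.58, Dusp1 at 1.90 ± 0.47, the ER chaperone gene Hyou1 at 1.57 ± 0.37 and Trib3 at 1.43 ± 0.31.
Cholesterol synthesis genes fell as a list (median -0.32, adjusted p = 0.000465), with Sqle at -0.95 ± 0.34 and Insig1 at -0.66 ± 0.22. T cell (median -0.40, adjusted p = 0.0175; Cd4 at -1.62 ± 0.44, n = 4 and 3), glia (median -0.36, adjusted p = 0.0181; Mbp at -0.65 ± 0.40) and fatty acid oxidation genes (median -0.19, adjusted p = 0.0376) fell too. With an estimated correlation these 4 lists had adjusted p = 0.549, 0.153, 0.601 and 0.632. The T cell call was lost without saline replicate 4 or EIH replicate 1 or 2, with adjusted p up to 0.200. The glia call was lost without saline replicate 1 or EIH replicate 1 or 4 (up to 0.372), and the fatty acid call without saline replicate 1, 2 or 3 or EIH replicate 1 or 2 (up to 0.112).
Genes of the secretory epithelium did not pass. Ttr lay at the upper end of the scale in every choroid plexus group, so its value of -0.01 ± 0.08 cannot show a change. Kl stood at -0.10 ± 0.48, Aqp1 at 0.05 ± 0.21, Slc4a5 at -0.57 ± 0.58 and Cldn1 at 0.25 ± 0.42. These errors pool all groups (Slc4a5 SD 0.374 in saline, 0.135 after EIH, 1.81 after AMPH at 1 day), so changes are not excluded. No call was made for choroid plexus epithelium (median -0.10, adjusted p = 0.454), fluid secretion (median -0.18, adjusted p = 0.150), barrier genes (median -0.13, adjusted p = 0.159), metallothioneins (median 0.11, adjusted p = 0.0561) or neutrophils (median 0.19, adjusted p = 0.558). Endothelium (median 0.27, adjusted p = 0.199), circadian clock (median 0.20, adjusted p = 0.339), cell cycle (median 0.15, adjusted p = 0.150), neurons (median 0.03, adjusted p = 0.746), erythroid (median 0.04, adjusted p = 0.963) and platelet genes (median -0.01, adjusted p = 0.626) were not called. By limma 35 of 10261 genes passed, 34 up and 1 down, and 1327 had an unadjusted p under 0.05. The count was 0 without any of saline replicates 1, 3 and 4 and EIH replicates 1, 2 and 4, 18 without saline replicate 2, 89 without EIH replicate 3 and 171 without AMPH 1 day replicate 2. It was 0 when pools with a recurring rat were left out and 1110 with array weights, of which 571 fell, so the direction of change beyond the strongest genes depends on the method. The heat shock, ER stress, immediate early, glucocorticoid, cytokine, p53 and cholesterol calls held without each array in turn. The p53 median was 0.20 without saline replicate 4, whose score of -0.36 lay below the 0.09 to 0.13 of the other saline pools.

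**Figure D1:**
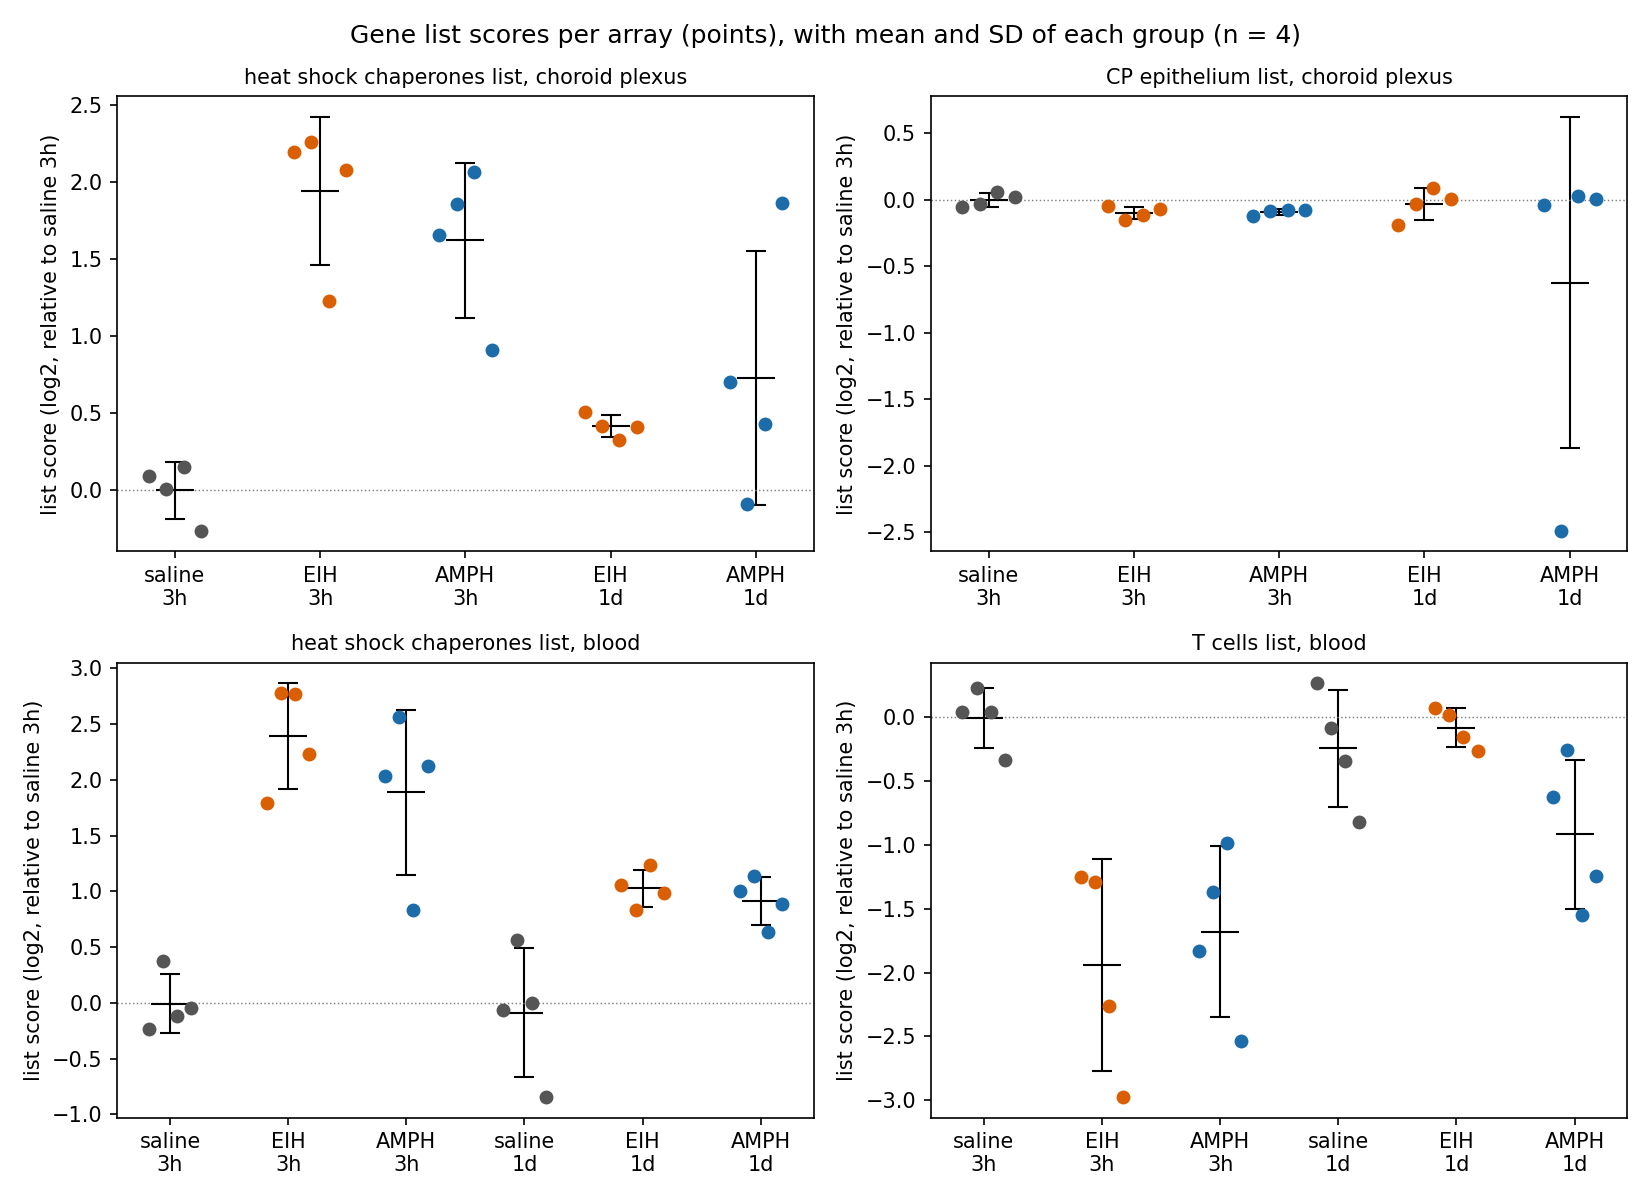
Scores of the heat shock and chaperone list and the choroid plexus epithelium list in choroid plexus, and of the heat shock and chaperone list and the T cell list in blood, on a log2 scale relative to saline at 3 h. Points are arrays and bars the mean and SD of each group (n = 4), and 1 AMPH pool of 1 day lies at -2.49 in the epithelium panel.

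At 3 h after AMPH, chaperone genes were again among the rises in the choroid plexus. Hspb1 rose by 3.88 ± 0.72 (adjusted p = 0.0423), with AMPH replicate 4 at 13.30 against 15.63 to 15.77 on the other AMPH arrays. There were rises of the cytosolic Hsp90 genes Hsp90aa1 and Hsp90ab1, by 1.92 ± 0.36 and 1.25 ± 0.22, and of P4ha1, a collagen prolyl hydroxylase gene, by 1.88 ± 0.33. The hyaluronan synthase gene Has1 rose by 2.85 ± 0.54 and Spry1, an inhibitor of receptor kinase signalling, by 1.69 ± 0.33. The zinc finger gene Plagl1 rose by 1.49 ± 0.25 and Cyp3a2 by 1.93 ± 0.27 (n = 3 and 2). Necab1 fell by 2.17 ± 0.37 and Pou1f1 by 2.15 ± 0.29 (n = 3 and 3). Piwil1, a gene for a small-RNA binding protein of the germ line, had an estimate of 11.44 ± 0.70 (adjusted p = 4.9e-05; n = 2 and 2). AMPH replicates 3 and 4 gave 14.67 and 14.19 for it, saline replicates 1 and 2 gave 3.18 and 2.80, at the low end of the scale, and the other cells were blank. If a blank means no signal, the AMPH arrays are split, and the estimate does not describe the group. Hspa1b stood at 5.42 ± 1.09 (adjusted p = 0.0524; second probe 0.43), Fos at 3.49 ± 0.72, Cebpd at 3.14 ± 0.62, Atf3 at 2.32 ± 0.53 and Il6 at 2.25 ± 0.53, none past the test.
As a list, heat shock and chaperone genes rose (median 1.48, adjusted p = 2.0e-20, and 0.0700 with an estimated correlation), with 3 of 23 up over all genes and 21 adjusted over the list alone. ER stress genes (median 0.73, adjusted p = 1.2e-08) rose with 11 of 19 up adjusted over the list alone, and immediate early genes (median 1.23, adjusted p = 1.4e-11) with 13 of 23. Glucocorticoid response genes (median 0.85, adjusted p = 2.1e-07) had 8 of 22 up in this way and p53 and apoptosis genes (median 0.59, adjusted p = 7.1e-06) 7 of 21. Cytokine genes (median 0.60, adjusted p = 3.4e-05) had 11 up and 2 down of 27. These 5 lists had adjusted p = 0.227, 0.0700, 0.0944, 0.0700 and 0.227 with an estimated correlation.
Cytotoxic lymphocyte genes fell as a list (median -0.76, adjusted p = 6.4e-05), with the chemokine gene Ccl5 at -2.20 ± 0.49, Klrb1a at -1.99 ± 0.72 and Klrk1 at -1.59 ± 0.56. T cell (median -0.59, adjusted p = 0.00947; Cd4 at -1.73 ± 0.47, n = 3 and 3), ependyma and cilia (median -0.44, adjusted p = 0.0300; Tekt4 at -1.35 ± 0.51) and cholesterol synthesis genes (median -0.37, adjusted p = 0.000125) fell too. With an estimated correlation the adjusted p of these 4 lists were 0.0700, 0.133, 0.753 and 0.407. The T cell call was lost without saline replicate 4 or AMPH replicate 4 (adjusted p up to 0.131), and the ependyma call without saline replicate 2 or AMPH replicate 2 or 3 (up to 0.0831). By limma 16 of 10263 genes passed, 14 up and 2 down, and 1536 had an unadjusted p under 0.05. The count was 0 without saline replicate 1 or 2 or AMPH replicate 3 and 1 without saline replicate 4 or AMPH replicate 1 or 2. It was 7 without saline replicate 3, 290 without AMPH replicate 4 and 350 without AMPH 1 day replicate 2. Fitting only the compared groups gave 0, a plain equal-variance test per gene 0, and leaving out pools that share a rat 1. Array weights gave 1354, 669 up and 685 down.
Set directly against each other at 3 h, AMPH and EIH differed in the choroid plexus by 1 gene of 10273, Piwil1 (10.62 ± 0.61; n = 2 and 4; adjusted p = 2.4e-05). In all 291 genes had an unadjusted p under 0.05. The count was 0 without AMPH replicate 3 or 4, which hold the values of Piwil1, and 2 without EIH replicate 3 or 4. NK and cytotoxic genes were lower after AMPH than after EIH as a list (median -0.54, adjusted p = 2.6e-05, and 0.0183 with an estimated correlation). Heat shock (median -0.21, adjusted p = 0.00935), metallothionein (median -0.13, adjusted p = 0.0382) and endothelium genes (median -0.22, adjusted p = 0.0288) were lower after AMPH, each with adjusted p = 0.932 with an estimated correlation. Across 9059 genes the EIH and AMPH differences from saline correlated at r = 0.758 (Spearman rho = 0.752), against 0.503 for simulated unchanged groups. The covariance was 0.185 against 0.0608 simulated. With the saline arrays split between EIH and AMPH r was 0.225 to 0.385, with too few genes called for any overlap. Genes are not independent replicates, and part of the excess may come from the shared controls. Of 34 genes up after EIH and 13 up after AMPH among the 10221 genes tested in both comparisons, 8 were shared. Independent lists would share 0.0432, a value that leaves out the shared controls.
At 1 day the choroid plexus was represented by EIH and AMPH pools alone, so each was set against saline at 3 h. Treatment there cannot be told apart from time and normalization set, and the median of all genes shifted by 0.17 for EIH and 0.11 for AMPH. The titles of the 4 EIH pools also call them controls while their source and treatment labels say EIH, and they were grouped by the latter. Pools 2 to 4 list 3 rats whose blood samples are titled and labelled EIH at 1 day, which favours EIH for these pools, while pool 1 lists no such rat. After AMPH, the DNA helicase gene Brip1 rose by 1.58 ± 0.21 (adjusted p = 0.00991). The phospholipase gene Pla1a rose by 1.18 ± 0.18 and Gpnmb, a glycoprotein gene of phagocytes, by 1.16 ± 0.18 (adjusted p = 0.0217 for both). With arrays scaled to the same median, 3 genes again passed, but 1 rose and 2 fell. Stress and inflammatory genes stood high without passing. Hspa1b was at 4.17 ± 1.09, Lbp, for the lipopolysaccharide binding protein, at 3.39 ± 0.86 and the protease inhibitor gene Slpi at 3.06 ± 0.78. The neutrophil genes S100a8 and S100a9 were at 2.64 ± 0.76 and 2.60 ± 0.78, and Fkbp5, a glucocorticoid target, at 1.51 ± 0.41.
Glucocorticoid response (9 of 22 up adjusted over the list alone; median 0.76, adjusted p = 8.2e-05), immediate early (median 1.04, adjusted p = 0.000129) and acute phase and complement genes (7 of 20; median 0.99, adjusted p = 0.000343) rose as lists after AMPH at 1 day. Cholesterol synthesis genes fell (6 of 18; median -0.35, adjusted p = 9.4e-07). These 4 calls held without each array in turn, but the cholesterol median shrank to -0.11 without AMPH replicate 2, whose score was -1.01 against -0.19 to -0.12 in the other pools. The acute phase median ran from 0.59 to 1.26. The 4 lists had adjusted p = 0.318, 0.529, 0.318 and 0.318 with an estimated correlation. Choroid plexus epithelium (median -0.66, adjusted p = 1.0e-07), fluid secretion (median -0.37, adjusted p = 0.000587) and ependyma and cilia genes (median -0.84, adjusted p = 0.000595) fell, and macrophage genes rose (median 0.71, adjusted p = 0.00963). Their adjusted p were 0.537, 0.537, 0.529 and 0.661 with an estimated correlation. All 4 calls were lost without AMPH replicate 2, with adjusted p of 0.147, 0.577, 0.0574 and 0.993 in that order. In that pool the epithelium score was -2.49, and Kl lay at 8.56 against 11.45 to 11.73 in the other AMPH pools. Without it the epithelium median was -0.01.
Neutrophil (5 of 20 up adjusted over the list alone; median 0.71, adjusted p = 0.0278), endothelium (median 0.54, adjusted p = 0.0261) and mural genes (median 0.56, adjusted p = 0.0368) rose, with adjusted p = 0.318, 0.537 and 0.661 with an estimated correlation. The neutrophil call was lost without saline replicate 2 or 3 or AMPH replicate 2 (adjusted p up to 0.476). The endothelium call was lost without saline replicate 3 or AMPH replicate 2 and the mural call without saline replicate 2 or AMPH replicate 2 (up to 0.556 and 0.993). In AMPH replicate 2 the neutrophil score was 2.01 and the mural score 1.87. Heat shock (median 0.48, adjusted p = 0.00914), cytokine (median 0.54, adjusted p = 0.0368) and p53 genes (median 0.38, adjusted p = 0.0284) rose and NK and cytotoxic genes fell (median -0.54, adjusted p = 0.00743). With an estimated correlation these had adjusted p = 0.687, 0.661, 0.537 and 0.318. The heat shock call was lost without AMPH replicate 4 (median 0.13, adjusted p = 0.752) and the NK call without AMPH replicate 1 or 3 (up to 0.0661). The cytokine call was lost without saline replicate 1, 2 or 3 or AMPH replicate 2 or 4 (adjusted p up to 0.599), and the p53 call without saline replicate 3 or 4 or AMPH replicate 1 or 4 (up to 0.133).
For AMPH at 1 day, limma called 3 of 10194 genes, and 1724 had an unadjusted p under 0.05. The count was 0 without AMPH replicate 1, 1 without saline replicate 1, 14 without saline replicate 3, and 9, 11 and 8 without AMPH replicates 2, 3 and 4. It was 0 under quantile normalization within the tissue, when only the compared groups were fitted and without pools that share a rat.
For EIH at 1 day against saline at 3 h, limma called 0 of 10267 genes and 1265 had an unadjusted p under 0.05. Hspa1b stood at 1.45 ± 1.09, Hspb1 at 0.34 ± 0.72, Pdk4, a fasting-induced kinase gene, at 0.77 ± 0.51 and Fkbp5 at 0.64 ± 0.41. The epithelial genes Kl and Aqp1 stood at 0.02 ± 0.48 and 0.04 ± 0.21, and Ttr at -0.02 ± 0.08, again at the upper end of the scale. A plain equal-variance test per gene also called 0, and array weights called 203. Without saline replicate 3 the count was 2, and without AMPH 1 day replicate 2 it was 12.
Cholesterol synthesis genes fell as a list after EIH at 1 day (median -0.12, adjusted p = 0.00388, and 0.888 with an estimated correlation), a call lost without EIH replicate 1 (adjusted p = 0.0973). Choroid plexus epithelium genes fell in the test, with a median of -0.00 (adjusted p = 0.0364, and 0.888 with an estimated correlation). That call was lost without saline replicate 2, 3 or 4 or EIH replicate 4 (up to 0.0953). NK and cytotoxic genes fell in the test while their median was 0.02 (adjusted p = 0.00892, and 0.505 with an estimated correlation), a call lost without EIH replicate 4 (0.112). The lectin receptor gene Klrd1 stood at -1.92 ± 1.02 and Ccl5 at -1.27 ± 0.49.
Within 1 day, where both groups lie in the same normalization set, AMPH against EIH gave 0 of 10204 genes by limma and 556 at an unadjusted p under 0.05. Array weights gave 3. Neutrophil genes were higher after AMPH as a list (median 0.76, adjusted p = 1.1e-05, and 0.00424 with an estimated correlation). Glucocorticoid response (median 0.54, adjusted p = 5.4e-07) and immediate early genes (median 0.61, adjusted p = 6.3e-06) were higher, and choroid plexus epithelium (median -0.69, adjusted p = 4.3e-05) and fluid secretion genes (median -0.38, adjusted p = 0.00272) lower. These 4 had adjusted p = 0.216, 0.505, 0.505 and 0.505 with an estimated correlation. In AMPH replicate 2, the pool with the low epithelium score, the neutrophil score was 2.01.
Blood at 3 h after EIH showed large rises of chaperone and inflammatory genes. Hspa1b rose by 7.16 ± 0.99 (adjusted p = 0.000178) and Hsph1 by 6.24 ± 0.61 (75.8-fold, 31.4 to 183; adjusted p = 5.8e-06). The second Hspa1b probe gave 1.48, and 3 EIH arrays lay at 15.94 to 15.99, near the upper end of the scale. Zfand2a, a heat-induced gene, rose by 5.59 ± 0.78, Hsp90aa1 by 4.69 ± 0.59, Hspb1 by 4.16 ± 0.68 and the Hsp40 gene Dnaja1 by 3.31 ± 0.28. The chemokine gene Cxcl2 rose by 5.96 ± 1.20 (n = 4 and 3), the inducible nitric oxide synthase gene Nos2 by 4.47 ± 0.71, the cyclooxygenase gene Ptgs2 by 4.17 ± 0.73, the alpha-defensin gene Defa5 by 5.14 ± 0.92 and Cdc42ep2 by 5.01 ± 0.74. The receptor gene Ephb6 fell by 3.72 ± 0.50 (n = 3 and 4; second probe -1.32), Nipsnap1 by 3.18 ± 0.61, the DNA repair gene Alkbh2 by 3.13 ± 0.65 and the DNA methyltransferase gene Dnmt3b by 3.11 ± 0.43.
Of 22 heat shock and chaperone genes 18 rose and 1 fell (median 2.42, adjusted p = 6.7e-17). Among immediate early genes 13 of 23 rose and 2 fell (median 1.13, adjusted p = 9.5e-07), with Jun at 4.26 ± 0.55, Atf3 at 3.85 ± 0.57 and Ier3 at 3.15 ± 0.45. Neutrophil genes rose (10 of 19, 14 adjusted over the list alone; median 1.92, adjusted p = 4.5e-08). Among them were the collagenase gene Mmp8 (2.71 ± 0.51), Retnlg (2.42 ± 0.36), Trem1 (2.32 ± 0.43) and the chemokine receptor gene Cxcr2 (1.35 ± 0.31). Macrophage and monocyte genes rose beside them (7 of 20; median 0.74, adjusted p = 0.00277), with Cd14 at 2.85 ± 0.59 and Ccr1 at 2.67 ± 0.59. T cell genes fell (14 of 17, 15 adjusted over the list alone; median -2.10, adjusted p = 6.8e-12). Cd6 fell by 2.47 ± 0.39 (second probe -0.78), Cd2 by 2.35 ± 0.44, Cd3g by 2.32 ± 0.41, Cd8a by 2.23 ± 0.29 and Cd3e by 2.04 ± 0.40. Cytokine, chemokine and adhesion genes rose (7 up and 1 down of 25; median 0.74, adjusted p = 0.000109), with Ccl2 at 3.61 ± 0.70 and Il1b at 1.65 ± 0.26. Endothelium genes rose too (2 of 17; median 0.72, adjusted p = 0.0172). Since neutrophil and T cell lists moved in opposite directions, the other changes in blood stand beside a changed mix of cell markers.
Acute phase and complement (5 of 20 up; median 1.13, adjusted p = 0.000474), hypoxia and glycolysis (6 of 22; median 0.34, adjusted p = 0.00187) and ER stress genes (3 of 19; median 0.31, adjusted p = 0.010) rose as lists. Their adjusted p with an estimated correlation were 0.0760, 0.184 and 0.224. EIH replicate 1 also carried liver transcripts, with a score of 4.01 against at most 1.06 on the saline arrays of 3 h, by a liver list chosen after seeing the data that shares 3 genes with the fixed lists. Glucocorticoid response (5 of 22; median 0.74, adjusted p = 0.010), metallothionein (4 of 19; median 0.29, adjusted p = 0.0152) and p53 genes (6 up and 2 down of 21; median 0.52, adjusted p = 0.0464) rose as well, with adjusted p = 0.226, 0.105 and 0.169 with an estimated correlation. Antigen presentation genes of MHC class II fell (6 of 11; median -1.24, adjusted p = 0.000175, and 0.100 with an estimated correlation), RT1-Da by 1.93 ± 0.35 and the class II transactivator gene Ciita by 1.39 ± 0.35. NK and cytotoxic (5 of 19; median -0.88, adjusted p = 0.00400) and B cell genes fell (3 of 12; median -0.71, adjusted p = 0.0328), with adjusted p = 0.257 and 0.341 with an estimated correlation. The B cell call was lost without saline replicate 1 or EIH replicate 4, and the p53 call without saline replicate 1 or 2 or EIH replicate 3 or 4 (adjusted p up to 0.120 and 0.101). S100a8 stood at 0.93 ± 0.41, Prf1, for perforin, at -0.92 ± 0.49 and Fkbp5 at -0.19 ± 0.34, none past the test. The erythroid gene Alas2 lay at the upper end of the scale in all blood groups. By limma 1250 of 9893 genes passed, 557 up and 693 down. Of them 843 changed at least 2-fold, and 2529 genes had an unadjusted p under 0.05. With only the compared groups fitted 588 rose and 561 fell.
AMPH at 3 h moved many of these gene groups in blood. Hspa1b rose by 6.54 ± 0.99 (adjusted p = 0.000983; second probe 1.62) and Hsph1 by 5.42 ± 0.61 (42.9-fold; adjusted p = 9.3e-05). Cxcl2 rose by 5.40 ± 1.20 (n = 4 and 3), Zfand2a by 4.29 ± 0.78, Hsp90aa1 by 3.99 ± 0.59, Hspb1 by 3.38 ± 0.68 and Dnaja1 by 2.83 ± 0.28. Defa5 rose by 4.45 ± 0.92 and the serpin gene Serpina3c by 4.46 ± 1.08. The carbonic anhydrase gene Car4 rose by 4.94 ± 1.42 (adjusted p = 0.0402; n = 4 and 3) and the amylase gene Amy1 by 4.45 ± 1.14 (adjusted p = 0.0191). Liver transcripts were high on most AMPH arrays. Scores were 2.52, 3.15, 0.98 and 5.46 on replicates 1 to 4 against at most 1.06 in saline at 3 h. The salivary gland score was 2.14 on replicate 2, against at most 1.87 in saline at 3 h and 2.14 at 1 day. The antiviral gene Mx2 fell by 2.85 ± 0.69 (n = 3 and 4), the T cell gene Cd5 by 2.46 ± 0.64, the lectin receptor gene Klrk1 by 2.43 ± 0.72 (n = 3 and 4) and Cnga1 by 2.59 ± 0.55.
Heat shock and chaperone genes rose (14 up and 1 down of 22; median 1.62, adjusted p = 1.1e-12). Immediate early genes rose (11 up and 1 down of 23; median 0.96, adjusted p = 6.0e-06), Jun by 3.49 ± 0.55 and Ier3 by 2.43 ± 0.45. ER stress genes rose (7 of 19; median 0.41, adjusted p = 9.0e-06), Trib3 by 1.90 ± 0.43 and Hyou1 by 1.34 ± 0.28, whose second probe gave 0.22. Hypoxia and glycolysis genes rose (9 of 22; median 0.68, adjusted p = 2.0e-06), such as Slc2a3 by 2.32 ± 0.58, and so did metallothionein and oxidative stress genes (4 of 19; median 0.44, adjusted p = 0.00513), Mt1 by 2.12 ± 0.54. The metallothionein median ran from 0.28 without AMPH replicate 1 to 0.59 without saline replicate 2. Among neutrophil genes 10 of 19 rose, and 13 adjusted over the list alone (median 1.85, adjusted p = 7.9e-10). Mmp8 rose by 2.59 ± 0.51, Retnlg by 2.25 ± 0.36 and S100a8 by 1.52 ± 0.41. Macrophage (4 up and 1 down of 19; median 0.72, adjusted p = 0.000877), cytokine (8 up and 1 down of 25; median 0.54, adjusted p = 0.000110) and endothelium genes (1 of 17; median 0.74, adjusted p = 0.0184) rose as lists. Acute phase and complement genes rose (7 of 20, 14 adjusted over the list alone; median 1.64, adjusted p = 5.0e-07), C3 by 1.34 ± 0.26 and Timp1 by 1.44 ± 0.31, beside the liver transcripts of the same arrays. T cell genes fell (11 of 17; median -1.81, adjusted p = 1.4e-11), Cd2 by 2.34 ± 0.44, Cd8a by 2.17 ± 0.29 and Cd3e by 2.01 ± 0.40. The first probe of Cd6 gave -2.15 and its second 0.15.
Cytotoxic lymphocyte (4 of 19; median -0.99, adjusted p = 3.4e-05), MHC class II (4 of 11; median -0.59, adjusted p = 0.0156), interferon response (4 of 28; median -0.19, adjusted p = 0.0435) and B cell genes (2 of 12; median -0.44, adjusted p = 0.0435) fell as lists. With an estimated correlation these had adjusted p = 0.103, 0.266, 0.527 and 0.413. Stroma and meninges (median 0.45, adjusted p = 0.0435), mural (median 0.80, adjusted p = 0.0366) and glia genes (median 0.49, adjusted p = 0.0280) rose, with adjusted p = 0.0692, 0.104 and 0.0829 with an estimated correlation. The MHC class II call was lost without AMPH replicate 2 (adjusted p = 0.0614). The interferon call was lost without saline replicate 1 or 2 or AMPH replicate 1 or 4 (up to 0.135) and the B cell call without saline replicate 1 or AMPH replicate 3 or 4 (up to 0.165). The stroma call was lost without saline replicate 1 or 2 or AMPH replicate 1, 3 or 4 (up to 0.101). The mural call was lost without saline replicate 1 or 2 or AMPH replicate 2 or 4 (up to 0.0655) and the glia call without saline replicate 1 or AMPH replicate 4 (up to 0.0742). Circadian clock (median 0.20, adjusted p = 0.923), cell cycle (median 0.09, adjusted p = 0.923), erythroid (median -0.00, adjusted p = 0.568), platelet (median 0.00, adjusted p = 0.932) and neuron genes (median 0.62, adjusted p = 0.0530) were not called. By limma 856 of 9863 genes passed, 501 up and 355 down. Of them 607 changed at least 2-fold, and 2199 genes had an unadjusted p under 0.05. The count was 448 without saline replicate 1, 541 without saline replicate 3, 502 without AMPH replicate 2 and 456 without AMPH replicate 4.

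**Figure D2:**
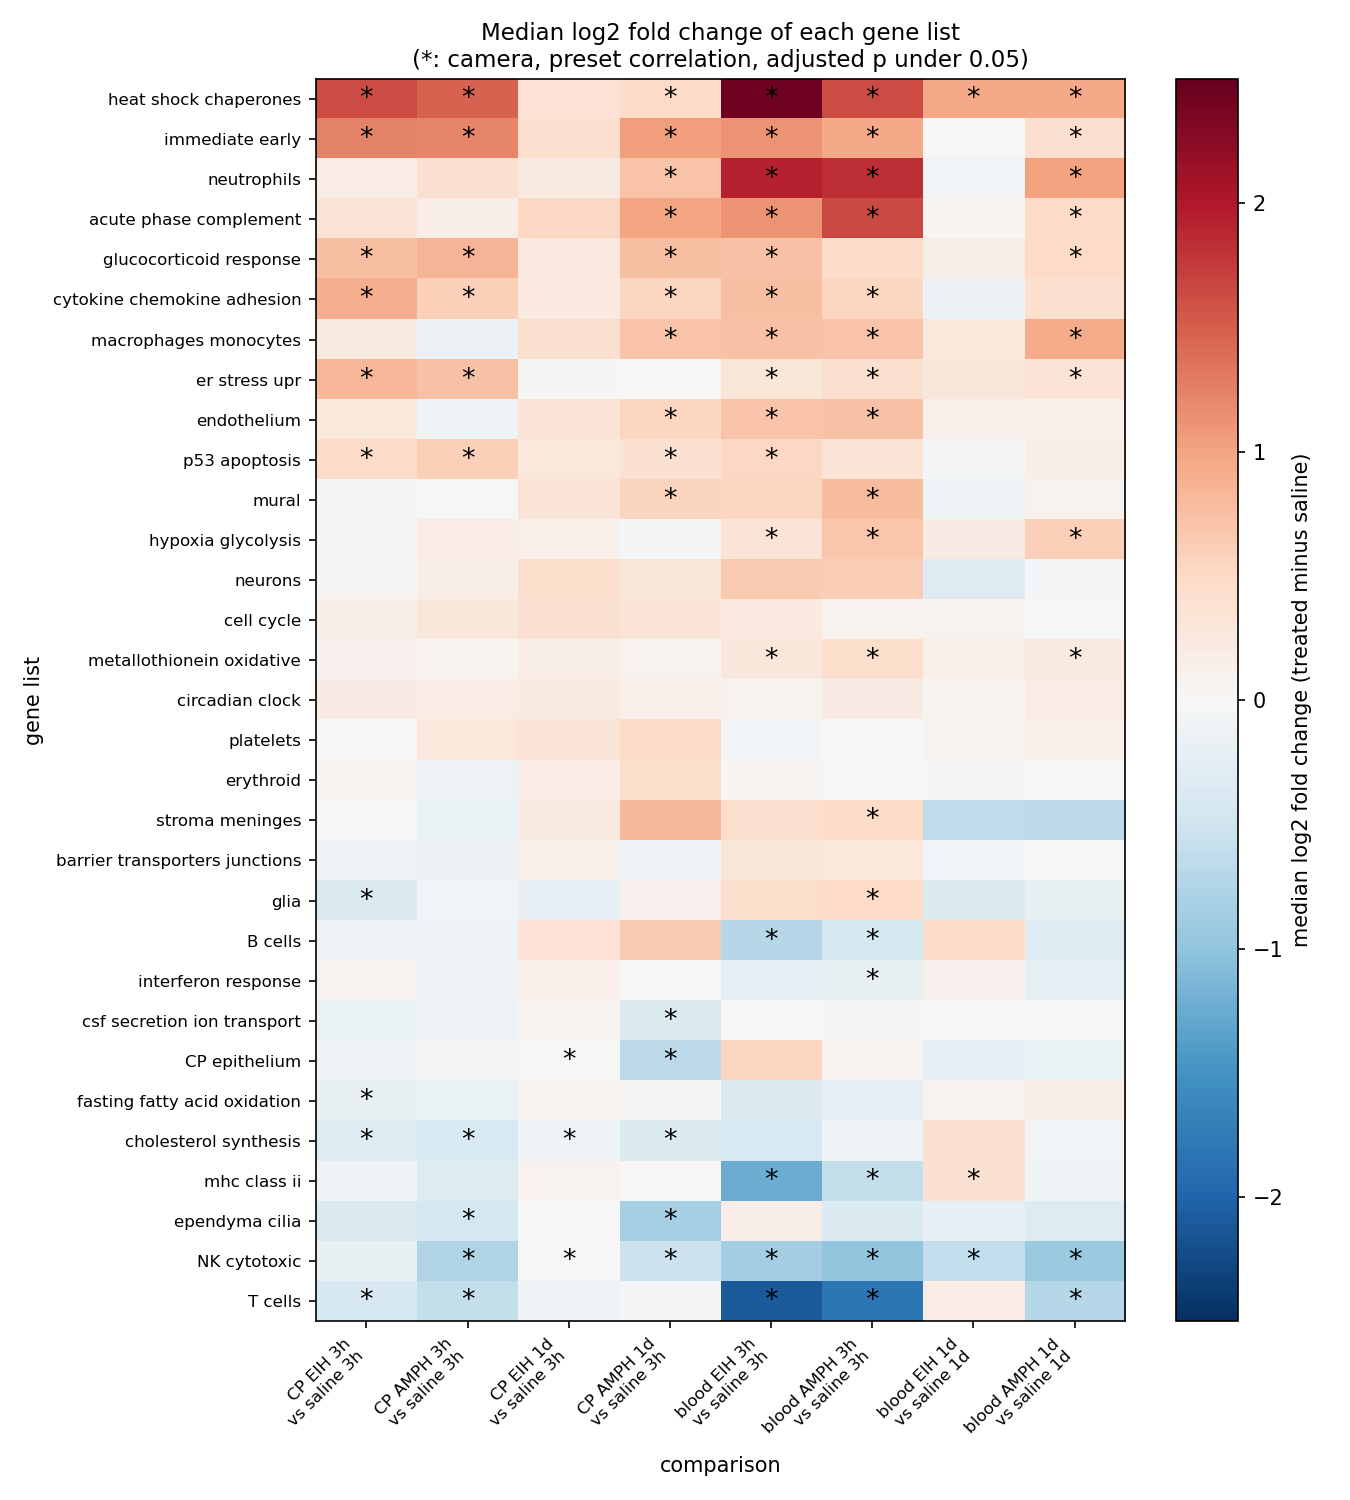
Median log2 difference from saline of each of the 31 gene lists (vertical axis) in the 8 comparisons of a treated group with saline (horizontal axis; CP, choroid plexus), as colours that stop at 2.5 in either direction. Stars mark an adjusted p under 0.05 by camera with the preset correlation, and the heat shock and chaperone list in blood at 3 h after EIH has a median of 2.42.

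AMPH and EIH at 3 h differed directly in 4 of 10068 blood genes, 3 higher after AMPH and 1 lower, with 960 at an unadjusted p under 0.05. The transcription factor gene Elf4 was higher by 2.53 ± 0.36 (adjusted p = 0.00855) and Ecel1 by 1.58 ± 0.26, and Zfp251 was lower, at -3.15 ± 0.47 (n = 4 and 3). The heat shock and chaperone list was lower after AMPH than after EIH (median -0.71, adjusted p = 6.7e-05, and 0.737 with an estimated correlation). The count was 1 without AMPH replicate 3, 2 without EIH replicate 3, 7 without EIH replicate 2 or AMPH replicate 4, 10 without AMPH replicate 2 and 11 without saline 1 day replicate 4. Across 7556 genes EIH and AMPH effects correlated at r = 0.797 (rho = 0.765) against 0.501 for simulated unchanged groups. Their covariance was 0.555 against 0.112 simulated, and splitting the saline arrays gave a correlation of 0.567 to 0.638. Of the genes called in each, 325 rose in both against 28.5 for independent lists, 294 fell in both against 25.1, and 0 moved in opposite directions. Independent lists leave out the shared controls. With the saline arrays split, 56 to 112 rose in both and 35 to 103 fell, against at most 8.11 and 5.81 for independent lists.

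**Figure D3:**
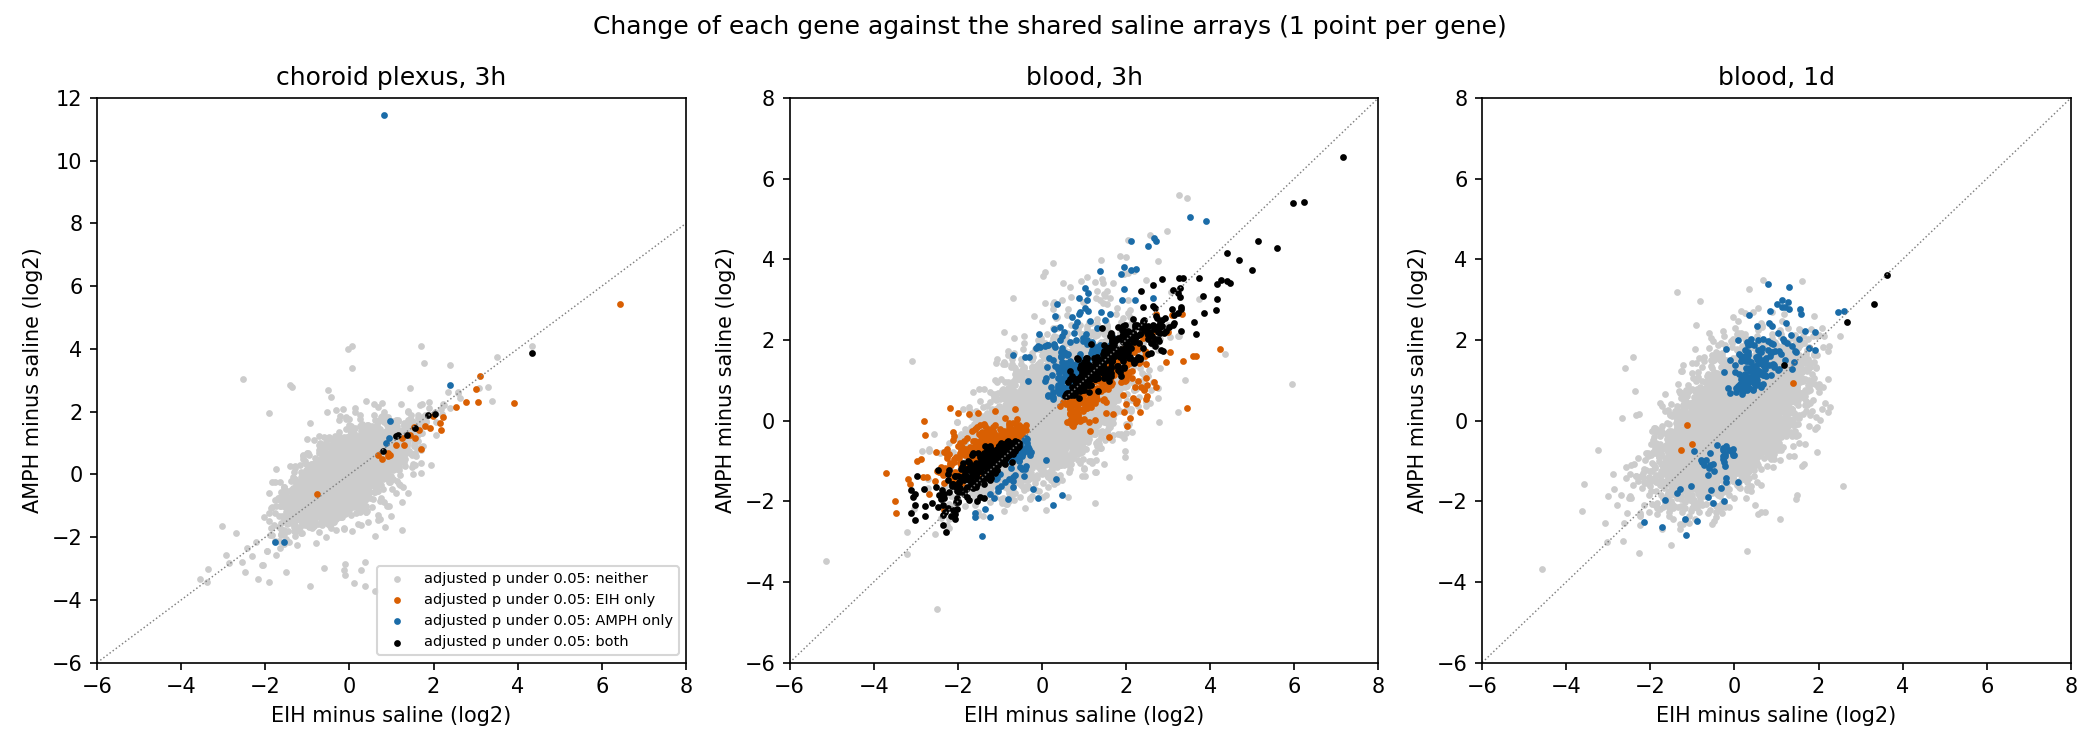
Log2 difference from saline after EIH (horizontal) and after AMPH (vertical) for choroid plexus at 3 h, blood at 3 h and blood at 1 day, with 1 point per gene and a dotted line of equal change. Colours mark genes past adjusted p 0.05 after EIH, AMPH, both or neither, and in blood at 3 h 325 genes rose in both.

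At 1 day after EIH, against saline of the same day, a small set of chaperone genes was high in blood. Hsph1 rose by 3.62 ± 0.61 (12.3-fold; adjusted p = 0.0257), Hsp90aa1 by 3.31 ± 0.59 (9.90-fold) and the Hsp40 genes Dnajb1 and Dnaja4 by 2.68 ± 0.44 and 1.19 ± 0.21. Tsnax, for a partner of translin, rose by 1.38 ± 0.26. The clathrin adaptor gene Ap2a1 fell by 1.26 ± 0.20 (adjusted p = 0.0243), Cyp4a2 by 1.13 ± 0.21 and Limd1 by 0.998 ± 0.19. Hspa1b stood at 0.98 ± 0.99 (second probe -0.71) and Hspb1 at -0.35 ± 0.68, neither past the test. As a list, heat shock and chaperone genes rose (4 of 23, 10 adjusted over the list alone; median 0.95, adjusted p = 1.1e-09, and 0.405 with an estimated correlation). MHC class II genes rose (median 0.39, adjusted p = 0.0217, and 0.518 with an estimated correlation), a call lost without saline replicate 1 or 4 or EIH replicate 4 (adjusted p up to 0.163). NK and cytotoxic genes fell (median -0.62, adjusted p = 0.00118, and 0.518 with an estimated correlation), with the granzyme genes Gzma at -1.97 ± 0.66 and Gzmk at -1.70 ± 0.61. Neutrophil (median -0.07, adjusted p = 0.353) and T cell lists (median 0.18, adjusted p = 0.995) were not called. By limma 8 of 9762 genes passed, 5 up and 3 down, and 1007 had an unadjusted p under 0.05. The count was 0 without saline replicate 1, 3 or 4 or EIH replicate 3 or 4 and 1 without EIH replicate 1. It was also 0 when only the compared groups were fitted and by the plain test per gene.
AMPH at 1 day raised chaperone and myeloid genes in blood. Hsph1 rose by 3.60 ± 0.61 (12.2-fold; adjusted p = 0.00605), Hsp90aa1 by 2.89 ± 0.59 and Dnajb1 by 2.44 ± 0.44. The integrin gene Itgam rose by 3.38 ± 0.82 (n = 4 and 3), Serpinb1a, an inhibitor of neutrophil proteases, by 3.32 ± 0.74 and the chemokine receptor gene Ccr1 by 2.93 ± 0.59. The colony-stimulating factor receptor genes Csf3r and Csf1r rose by 1.89 ± 0.33 and 1.16 ± 0.27, and Cxcr2 by 1.20 ± 0.31. The second probe of Csf1r had no value after AMPH, and the mean over its probes gave 2.80. Dab2 rose by 3.00 ± 0.74, Prg4, for lubricin, by 2.81 ± 0.48, Lbp by 2.72 ± 0.64 (n = 4 and 3) and Sgk1, a glucocorticoid target, by 2.03 ± 0.41. Dusp1, a phosphatase gene induced by glucocorticoids and stress, rose by 2.78 ± 0.42 (adjusted p = 0.00605). It fell in saline between 3 h and 1 day by 1.89 ± 0.42, so the level of the 1 day saline arrays enters its rise. The cartilage collagen gene Col9a2 fell by 2.85 ± 0.36 (adjusted p = 0.00199; n = 4 and 3), Aox2 by 2.63 ± 0.64 (n = 3 and 4), Zbtb39 by 2.48 ± 0.51 and the synaptic adhesion gene Nlgn1 by 2.52 ± 0.49, whose second probe gave 0.40.
Macrophage and monocyte genes rose as a list (6 of 20, 10 adjusted over the list alone; median 0.92, adjusted p = 1.7e-06, and 0.000139 with an estimated correlation). Heat shock (7 of 23; median 0.95, adjusted p = 3.8e-06), neutrophil (2 of 19, 8 adjusted over the list alone; median 1.01, adjusted p = 0.000265) and glucocorticoid response genes rose (3 of 21; median 0.50, adjusted p = 0.00132; Cebpd 1.47 ± 0.28). Hypoxia and glycolysis (2 of 21, 10 adjusted over the list alone; median 0.60, adjusted p = 0.000542; Ldha 1.02 ± 0.25) and immediate early genes (3 of 22; median 0.43, adjusted p = 0.00115; Junb 1.32 ± 0.31) rose too. With an estimated correlation these 5 had adjusted p = 0.259, 0.234, 0.234, 0.234 and 0.234. The immediate early median ran from 0.37 to 0.70 when 1 array was left out. ER stress (median 0.35, adjusted p = 0.0203), metallothionein (median 0.22, adjusted p = 0.0310) and acute phase genes (median 0.48, adjusted p = 0.0442) rose, with adjusted p = 0.319, 0.234 and 0.322 with an estimated correlation. T cell (median -0.70, adjusted p = 0.000331) and NK and cytotoxic genes fell (median -0.93, adjusted p = 0.000542), with adjusted p = 0.319 and 0.272 with an estimated correlation. The ER stress call was lost without saline replicate 2 or AMPH replicate 4 (adjusted p up to 0.155). The metallothionein call was lost without saline replicate 1 or 2 or AMPH replicate 3, and the acute phase call without saline replicate 2 or 3 or AMPH replicate 3 (up to 0.125 and 0.193). In all 204 of 9797 genes passed, 161 up and 43 down, and 1750 had an unadjusted p under 0.05. The count was 404 without saline replicate 1, 103 without saline replicate 3, 82 without saline replicate 4, 58 without AMPH replicate 3 and 28 without AMPH replicate 4. It was 0 when only the compared groups were fitted and 1 by the plain test per gene.
Against EIH at 1 day, AMPH left 0 of 9848 blood genes past limma's test and 1162 at an unadjusted p under 0.05, with 0 by the plain test per gene. The count was 25 without AMPH replicate 1 and 30 without AMPH replicate 2. Neutrophil genes were higher after AMPH as a list (8 of 19 adjusted over the list alone; median 1.36, adjusted p = 1.0e-08, and 0.00804 with an estimated correlation). Macrophage genes were higher as well (6 of 20; median 0.60, adjusted p = 6.3e-06). Glucocorticoid response (median 0.70, adjusted p = 0.000265) and immediate early genes (median 0.59, adjusted p = 0.000863) were higher, and T cell (median -0.996, adjusted p = 6.3e-06), B cell (median -0.72, adjusted p = 0.00111) and MHC class II genes (median -1.03, adjusted p = 0.000265) lower. These 5 had adjusted p = 0.172, 0.172, 0.178, 0.178 and 0.172 with an estimated correlation. Across 7080 genes EIH and AMPH effects at 1 day correlated at r = 0.605 (rho = 0.587) against 0.501 simulated, with a covariance of 0.227 against 0.119. Saline spread was larger (median SD 0.635 against 0.395 and 0.482), so sharing may explain the excess. Split saline arrays gave r = 0.0815 to 0.239. Among called genes 4 rose in both, against 0.0837 for independent lists, and 0 did with the saline arrays split.
Between the saline groups of blood, time and normalization set changed together, and the median of all genes shifted by 0.11. Mrgprb5 rose from 3 h to 1 day by 4.49 ± 0.68 (n = 2 and 2), the protocadherin gene Pcdhb4 by 2.60 ± 0.59, the zinc transporter gene Slc39a5 by 2.54 ± 0.52 and Ntm by 2.52 ± 0.56 (n = 3 and 4). Dusp1 fell by 1.89 ± 0.42, Ly6g6c by 1.61 ± 0.36, Stx5 by 1.60 ± 0.32 and Cfl1 by 1.45 ± 0.23. Stroma genes rose (median 0.80, adjusted p = 0.0357, and 0.0806 with an estimated correlation) and hypoxia genes fell (median -0.39, adjusted p = 0.0357, and 0.650 with an estimated correlation) as lists. Of 9707 genes 58 passed, 46 up and 12 down. With arrays scaled to the same median 28 rose and 111 fell, so the direction of these calls rests on the scaling. The count was 6, 7, 14 and 17 without saline 3 h replicates 1 to 4, and 261, 21, 22 and 34 without saline 1 day replicates 1 to 4.
The effects of each exposure at 3 h differed between choroid plexus and blood by a test of the difference itself (choroid plexus minus blood). For EIH 602 of 9813 genes differed, 378 with the higher change in choroid plexus and 224 with the lower. Nos2 at -4.93 ± 0.79, Cdc42ep2 at -4.66 ± 0.81 and Zfand2a at -4.61 ± 0.89 lay lower in choroid plexus, and the chemokine gene Ccl20 at 4.23 ± 0.85 higher. T cell (median 1.56, adjusted p = 1.5e-05) and neutrophil lists (median -1.29, adjusted p = 0.000294) differed, with adjusted p = 0.271 and 0.195 with an estimated correlation. For AMPH 308 of 9788 genes differed, 148 higher and 160 lower, with Serpina3c at -5.54 ± 1.28 and Cd8a at 3.04 ± 0.67 (3 arrays in each choroid plexus group). The T cell list differed in the same direction (median 1.22, adjusted p = 0.000200, and 0.335 with an estimated correlation). The AMPH count was 205 without choroid plexus saline replicate 3, 199 and 171 without choroid plexus AMPH replicates 2 and 3 and 488 without choroid plexus AMPH 1 day replicate 2. It was 173 without blood saline replicate 1, 465 and 187 without blood AMPH replicates 3 and 4 and 465 without blood saline 1 day replicate 4.
In blood, EIH effects at 1 day differed from those at 3 h (1 day minus 3 h) for 859 of 9483 genes, 486 higher and 373 lower. Cxcl2 at -6.59 ± 1.81, with blanks on some arrays, Defa5 at -6.32 ± 1.30 and Hspa1b at -6.18 ± 1.41 had the lower effect at 1 day, and the lymphocyte transcription factor gene Ets1 at 3.99 ± 1.09 the higher. Heat shock (median -1.0, adjusted p = 0.000110), neutrophil (median -2.09, adjusted p = 5.1e-07), T cell (median 2.11, adjusted p = 6.5e-08) and MHC class II lists (median 1.94, adjusted p = 4.9e-05) differed. Their adjusted p, with an estimated correlation, were 0.237, 0.0592, 0.105 and 0.105. The count was 457 without saline 3 h replicate 1 and 469 without EIH 1 day replicate 4. For AMPH 36 of 9491 genes differed, 2 higher and 34 lower, with Pcdhb4 at -4.67 ± 0.84 and Col9a2 at -4.17 ± 0.49, again with blanks. The stroma list differed (median -0.92, adjusted p = 0.00897, and 0.0206 with an estimated correlation), and so did the heat shock list (median -0.73, adjusted p = 0.0127, and 0.580 with an estimated correlation). In saline itself the stroma list rose from 3 h to 1 day (median 0.80) and Pcdhb4 rose by 2.60 ± 0.59, so the level of the saline arrays enters both differences. The AMPH count was 91 without saline 1 day replicate 1, and 22 and 119 without AMPH 1 day replicates 2 and 3. Since the 1 day and 3 h arrays appear to form separate normalization sets, each effect was taken within its own set.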

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

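All tests of explanations and all counts of other splits in this part were chosen after the results were seen; the comparisons between tissues and times were planned.
In 323 groups of 4 arrays tested for an array far from the other 3, 25 held one, where chance gives about 1 in 20, or 16.15. For single genes (log2 intensity), choroid plexus EIH 3 h replicate 3 was low for Hspa1b at 11.01 and Dnajb1 at 10.36, AMPH 3 h replicate 4 low for Hspb1 at 13.30 and AMPH 1 day replicate 2 low for Kl at 8.56. In blood, EIH 3 h replicate 1 was low for Hspa1b at 14.37 and Hspb1 at 11.06, and EIH 1 day replicate 2 high for Prf1 at 10.83. For list scores (log2 relative to saline at 3 h), choroid plexus saline replicate 4 stood apart in cytokine genes at -0.11 and p53 genes at -0.36, EIH 3 h replicate 3 in neutrophil genes at 0.41, EIH 3 h replicate 2 in mural genes at 0.80, AMPH 3 h replicate 1 in epithelium genes at -0.12, EIH 1 day replicate 1 in immediate early genes at 0.61 and macrophage genes at 0.92, and AMPH 1 day replicate 3 in p53 genes at 0.22. Choroid plexus AMPH 1 day replicate 2 stood apart in 5 lists: cholesterol synthesis at -1.01, fluid secretion at -1.47, epithelium at -2.49, NK and cytotoxic at 0.37 and neutrophils at 2.01. In blood the scores were -0.26 for endothelium (saline 3 h replicate 1), 0.36 for mural genes (saline 3 h replicate 4), 0.37 for glia (saline 3 h replicate 2), 0.34 for endothelium (AMPH 3 h replicate 3) and 0.23 for interferon genes (AMPH 1 day replicate 1).
The first pattern weighed is choroid plexus AMPH 1 day replicate 2. A failed array is argued against by its 4.13% of blank cells, inside the 1.21% to 6.38% of the other choroid plexus arrays. An AMPH effect on the epithelium as the cause is argued against by the other 3 pools, whose mean epithelium score of -0.00035 lay inside the saline range of -0.05 to 0.06. A different tissue mix stays open. In this pool 6 lists (stroma, mural, endothelium, erythroid, macrophages, neutrophils) were highest of its group, stroma at 2.32 against -0.22 to 0.46. So were platelets, B cells, neurons, glia and NK genes, but not T cells, so no tissue is singled out. Less epithelium or a real change in 1 pool was not tested. The pool also lists a rat number that appears in choroid plexus saline 3 h replicate 4, and these 2 arrays had the lowest weights in choroid plexus (0.0583 and 0.207). A wrong rat number or label stays open and was not tested.
In the second pattern, part of the chaperone genes stood high in blood 1 day after EIH while Hspa1b, at 7.16 at 3 h, stood at 0.98. A shift to neutrophils is argued against by their list median of -0.065 after EIH at 1 day, and 3 h rats among the 1 day arrays by 5 other genes that kept -0.843% of their 3 h rise. Low saline arrays at 1 day as the whole cause are argued against by the 8 treated arrays, EIH and AMPH together. Their mean score lay 0.98 above that of saline at 3 h (95% interval 0.69 to 1.27), across the normalization sets. As part of the cause they stay open, since the saline score of 1 day lay -0.080 from that of 3 h with a 95% interval of -0.86 to 0.70. A lasting response to the treatments stays open too and was not tested. Hsph1 went from 6.24 to 3.62 and Dnajb1 from 2.94 to 2.68.
The third pattern is liver and salivary gland transcripts in blood, by lists of 26 and 17 genes chosen after seeing the data (24 and 10 measured, 3 and 1 of them also in fixed lists). A common source of both is argued against, since 1 array was among the 4 highest by both scores. Tissue carried into single samples may account for part: on saline 1 day replicate 2, which had the highest Alb of its group (12.77), 84.2% of the other liver genes were highest too. Release of liver RNA after AMPH stays open, with an exact two-sided permutation p = 0.0571 at 3 h and 0.514 at 1 day. Alb reached 15.07 on AMPH 3 h replicate 4.
Differences between tissues (choroid plexus minus blood) and times (1 day minus 3 h) in the same treatment effect were found by a test of the difference. EIH at 3 h differed between tissues for 602 genes, among them Kprp 4.64, Ccl20 4.23, Ephb6 3.71, Cbx7 3.37, Car4 -4.55, Zfand2a -4.61, Cdc42ep2 -4.66 and Nos2 -4.93. Lists that differed had medians of 0.54 for ER stress, 0.80 for MHC class II, -0.38 for hypoxia, -0.53 for macrophages, -1.29 for neutrophils and 1.56 for T cells, with adjusted p from 0.195 to 0.821 with an estimated correlation. For AMPH 308 genes differed, among them Nr1h4 3.06, Cd8a 3.04, Cnga1 2.99, Id3 2.64, Prdx5 -4.79, Dnase1 -5.09, Car4 -5.34 and Serpina3c -5.54. Its lists had medians of -1.55 for acute phase, -0.53 for hypoxia, -0.95 for endothelium, -0.71 for glia, -0.85 for macrophages, -1.15 for neutrophils and 1.22 for T cells, with adjusted p from 0.287 to 0.421 with an estimated correlation. The T cell gene Cd3e lay near the low end of the scale in choroid plexus, so the level enters the T cell differences between tissues. In blood, the EIH effect differed between times for 859 genes, among them Ets1 3.99, Ap3m2 3.96, Klhl8 3.93, Jup 3.84, Hcar2 -5.70, Hspa1b -6.18, Defa5 -6.32 and Cxcl2 -6.59. List medians were -1.0 for heat shock, -1.25 for immediate early, -0.58 for glucocorticoid response, -0.88 for cytokines, -1.12 for acute phase, 1.94 for MHC class II, 0.67 for cholesterol synthesis, -0.64 for stroma, -0.97 for neurons, -2.09 for neutrophils, 2.11 for T cells and 1.24 for B cells (adjusted p from 0.0592 to 0.322 with an estimated correlation). The AMPH effect differed between times for 36 genes, among them Tsnax 2.05, Cdr2 1.71, Gulo -3.92, Col9a2 -4.17, Slc39a5 -4.39 and Pcdhb4 -4.67. Its list medians were -0.73 for heat shock, -0.78 for acute phase, 0.46 for fatty acid oxidation, -0.92 for stroma, -0.76 for glia, -0.74 for neutrophils and 0.97 for T cells. With an estimated correlation only stroma held (adjusted p = 0.0206), and the other 6 had 0.160 to 0.580. Since stroma, Pcdhb4 and Slc39a5 rose in saline from 3 h to 1 day, the control arrays enter these differences.
Probes with no gene symbol, outside the comparisons of the report, also differed: 3 after EIH at 3 h and 1 after EIH at 1 day in choroid plexus, and in blood 86 after EIH and 42 after AMPH at 3 h, 1 between AMPH and EIH at 3 h, 1 after EIH and 19 after AMPH at 1 day, and 12 between the saline groups.
Other splits of the compared arrays were counted, the real one included, as a test of chance. The real split alone, 1 of 35, called as many genes for choroid plexus EIH 3 h (real 35, highest other 0) and AMPH 3 h (16 and 2). So it was for blood EIH 3 h (1250 and 6), AMPH 3 h (856 and 1), EIH 1 day (8 and 2) and AMPH 1 day (204 and 42). Saline 1 day against 3 h (58 and 4) and the tissues (5581 and 2) gave the same. Since 1 of 35 is the lowest share these splits can reach, and many comparisons were counted, chance is not excluded. Mixed splits also add any real difference to the spread, which lowers their counts. More than the real split reached as many genes for AMPH against EIH at 3 h in choroid plexus (2 of 35, real 1, highest other 2) and blood (3 of 35, 4 and 8). Choroid plexus AMPH 1 day against saline was like these (2 of 35, 3 and 3). Where the real count was 0, all 35 of 35 splits must give as many, so nothing was tested: choroid plexus EIH 1 day (highest other 0) and AMPH against EIH at 1 day in choroid plexus (7) and blood (1). For the differences between effects 100 splits were drawn: 2 gave as many for EIH between tissues (602 and 724), 1 for AMPH between tissues (308 and 57), 1 for EIH between times (859 and 447) and 2 for AMPH between times (36 and 38). The split with 724 kept the blood labels and mixed those of choroid plexus, so the EIH count between tissues rests mainly on the blood arrays.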

How the results depend on the processing

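The fits named above as added, and the block of shared rats, were chosen after seeing the data. All others were planned. No named gene changed sign while called. The NK and cytotoxic list after choroid plexus EIH at 1 day, called with a median of 0.02, had -0.16 under quantile normalization and -0.02, -0.29 and -0.08 without saline replicate 4, EIH replicate 1 and EIH replicate 3, and was called each time. The epithelium list there turned from -0.00322 to 0.00456 without EIH replicate 1. Of 10377 values of named genes under alternatives, 903 lost the call and 272 gained it. The count between tissues under saline (5581) stayed within 1.5 times under each alternative run, and leaving out liver and salivary gland genes moved no count by more than that. With arrays that share a rat as a random replicate block (consensus correlation 0.0831 for the tissues and 0.168 for the differences between them), the counts were 5596 for the tissues, 761 [602] for the EIH difference and 386 [308] for the AMPH difference. Array signal over background limits dim genes: the table gives no background flags, and blank cells take genes out of some groups. Where a count moved without the number of genes or arrays changing, the cause was not tested.
Counts are given as called genes by setting, with the reported count in brackets. With array weights: choroid plexus EIH 3 h 1110 [35], AMPH 3 h 1354 [16], EIH 1 day 203 [0], AMPH 1 day 12 [3] and AMPH against EIH 1 day 3 [0]; blood EIH 3 h 1956 [1250], AMPH 3 h 1532 [856], EIH 1 day 85 [8], AMPH 1 day 135 [204], AMPH against EIH 1 day 55 [0] and saline 1 day against 3 h 203 [58]; differences between tissues 1439 [602] for EIH and 1213 [308] for AMPH, and between times 1625 [859] and 213 [36]. With an intensity trend and robust spread: choroid plexus EIH 3 h 73, AMPH 3 h 59 and AMPH 1 day 5; blood AMPH against EIH 3 h 18 [4], EIH 1 day 16, AMPH 1 day 379, AMPH against EIH 1 day 63, saline 97 and the AMPH difference between times 56. Without the dimmest 25% of genes: choroid plexus EIH 3 h 76, AMPH 3 h 44 and AMPH 1 day 5; blood AMPH against EIH 3 h 18, EIH 1 day 13 and AMPH 1 day 361.
With only the compared groups fitted: choroid plexus EIH 3 h 68, AMPH 3 h 0, AMPH against EIH 3 h 0 [1] and AMPH 1 day 0; blood AMPH against EIH 3 h 1, EIH 1 day 0, AMPH 1 day 0 and saline 0. By the plain equal-variance test per gene: choroid plexus EIH 3 h 161 and AMPH 3 h 0; blood AMPH against EIH 3 h 2, EIH 1 day 0, AMPH 1 day 1 and saline 2. Without pools that share a rat: choroid plexus EIH 3 h 0, AMPH 3 h 1, EIH 1 day 246, AMPH 1 day 0 and AMPH against EIH 1 day 184. The 246 and 184 rest on 1 EIH pool, so they test nothing. With genes measured on every array: choroid plexus AMPH 3 h 30 and AMPH against EIH 3 h 0; blood AMPH against EIH 3 h 18, EIH 1 day 13, AMPH 1 day 401, AMPH against EIH 1 day 2 and saline 118. Under quantile normalization within the tissue, choroid plexus AMPH 1 day gave 0 and blood saline 12; the same 75th percentile gave 1 for choroid plexus AMPH 1 day; the same median gave 139 for blood saline. Testing every probe gave 9 for choroid plexus AMPH 3 h, and the mean over probes 5 for blood EIH 1 day and 32 for blood saline. Directions turned: choroid plexus EIH 3 h went from 34 up and 1 down to 539 up and 571 down with array weights or 66 up and 95 down by the plain test. With only the compared groups fitted most rose (42 of 68). AMPH 3 h there went from 14 up and 2 down to 669 up and 685 down with array weights. At the same median blood saline went from 46 up and 12 down to 28 up and 111 down, and choroid plexus AMPH 1 day from 3 up and 0 down to 1 up and 2 down. Blood saline gave 4 up and 8 down under quantile normalization and 27 up and 27 down at the same 75th percentile. The plain test gave 0 up and 2 down there. Blood EIH 3 h went from 557 up and 693 down to 588 up and 561 down with only the compared groups fitted, and AMPH against EIH from 3 up and 1 down to 0 up and 1 down. Blood EIH 1 day went from 5 up and 3 down to 31 up and 54 down with array weights, to 5 up and 6 down without EIH replicate 2 and to 0 up and 1 down without EIH replicate 1. The AMPH difference between tissues, 148 up and 160 down, was near even and went to 226 up and 220 down with genes measured on every array, with similar turns when single arrays were left out.
Leaving out 1 array at a time gave, lowest to highest: choroid plexus EIH 3 h 0 to 171, AMPH 3 h 0 to 350, AMPH against EIH 3 h 0 to 2, EIH 1 day 0 to 12, AMPH 1 day 0 to 14 and AMPH against EIH 1 day 0 to 0; blood EIH 3 h 836 to 1518, AMPH 3 h 448 to 1051, AMPH against EIH 3 h 1 to 11, EIH 1 day 0 to 11, AMPH 1 day 28 to 404, AMPH against EIH 1 day 0 to 30 and saline 6 to 261; tissues 5133 to 5716; differences between tissues 404 to 787 for EIH and 171 to 488 for AMPH, and between times 457 to 899 and 22 to 119.
List calls in comparisons with saline numbered 86, against 20 with an estimated correlation, 89 under quantile normalization and 58 by fry. For Hspa1b in choroid plexus after EIH at 3 h, 10 of 20 alternatives kept the call, with adjusted p from 0.000993 to 0.318 and log2 differences from 3.75 to 7.59. For Hspb1 there, 13 of 20 did, with log2 differences from 4.22 to 4.55. Splitting the saline arrays gave correlations of 0.225 to 0.385 in choroid plexus and 0.567 to 0.638 in blood at 3 h, and of 0.105 to 0.373 and 0.0815 to 0.239 at 1 day. All are lower than with shared controls.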

Other observations

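All overlaps in this part were examined after the results were seen. Of 34 genes that rose in the choroid plexus after EIH at 3 h and were also tested in blood, 17 rose in blood too, against 1.93 for independent lists, and 29 of the 34 lay above saline there. Of the 17, 10 belong to the heat shock and chaperone list, which had 22 members tested in both tissues. Among the shared genes were Hspa1b (6.43 in choroid plexus and 7.16 in blood), Hsph1 (2.78 and 6.24), Hsp90aa1 (2.02 and 4.69), Hsp90ab1 (1.37 and 2.32), Hspb1 (4.35 and 4.16), the mitochondrial pair Hspd1 (2.23 and 3.65) and Hspe1 (1.80 and 2.75), and Serpinh1, for a collagen chaperone of the endoplasmic reticulum (1.91 and 1.37). The others included Hmox1 (3.90 and 2.82), Atf3 (3.07 and 3.85), Cebpd (3.10 and 1.17), the bacterial pattern receptor gene Cd14 (1.10 and 2.85), Bst2 (1.64 and 2.15) and P4ha1 (1.87 and 2.21).
After AMPH, 5 genes rose in both tissues against 0.659: Hspb1 (3.88 and 3.38), Hsp90aa1 (1.92 and 3.99), P4ha1 (1.88 and 2.02), Arid5a (1.25 and 1.18) and the transcription factor gene Ets2 (1.01 and 1.53). No gene was called in opposite directions in the tissues after either exposure. Over all genes tested in both tissues the correlation across genes was weak, at r = 0.147 for EIH and 0.108 for AMPH, and genes are not independent replicates. Since 17 blood rats also gave tissue to a pool, the tissues are not independent samples of rats, and the overlap was not tested beyond these counts.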
